A study of Mus musculus with 8 samples.

How the data were processed

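RNA sequencing was analysed for 8 libraries of hair follicle stem cells from the back skin of male mice at postnatal day 70. Per the labels' protocols, cells were sorted as positive for integrin alpha 6 and CD34 and negative for Sca-1 and DAPI. The knockout cells were also gated on YFP, and the wild-type (WT) cells were not. RNA was extracted with TRIzol LS and Direct-zol columns, and libraries were made with a TruSeq mRNA kit and sequenced as paired ends on HiSeq instruments, per the labels. The 4 groups (WT, NFIB-cKO, NFIX-cKO and NFIB/X-dKO) held 2 libraries each, and every library carried another animal number in its title, so replicates were taken as separate animals. Groups were taken from the titles.

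The authors deposited a table of TPM, transcript abundance scaled to the same sum in every library, for all 8 libraries, with 46609 features, of which 46517 were genes and 92 were spike-in sequences that took 0% of the TPM. Gene tables with expected counts, TPM and mean transcript lengths were used for 5 libraries, as deposited by the authors: NFIB-cKO 85 and both libraries of NFIX-cKO and NFIB/X-dKO. The expected counts were made with RSEM 1.2.30 and Bowtie2 2.2.9 on the mouse build mm10 (GRCm38), per the submitters' processing notes, and the TPM in the shared table equalled that in the gene tables (largest difference 0). The annotation release and any filter on reads were not given in the sources used here. The deposited length and effective length of a gene differed by 50 bases in every gene table and entered no test. Expected count totals ran from 57173266 to 66854625 in the 5 libraries. The depth of WT 34, WT 82 and NFIB-cKO 81 was unknown, since TPM keeps no depth, and no interval was computed for them. All 8 columns of the TPM table were matched to libraries by title, and 0 were left unmapped.

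The main test was limma 3.58.1 (R 4.3.3) on log2(TPM + 1), with a pseudocount of 1, a variance trend and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Genes entered with a TPM of at least 1 in at least 2 libraries, which left 15434 genes. All 8 libraries were fitted together, so the groups shared 1 estimate of the spread, with 4 residual and 3.10 prior degrees of freedom. Fold changes are on the log2(TPM + 1) scale, which understates the change of weakly expressed genes. The 6 contrasts were each knockout group against WT, NFIB/X-dKO against each of the other knockout groups, and the non-additive contrast, which is the NFIB/X-dKO change from NFIB-cKO minus the NFIX-cKO change from WT. For NFIB/X-dKO against NFIX-cKO, the groups with gene tables for both libraries, edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr) was run on expected counts rounded to whole numbers. Its 4 libraries left 18349 genes. Gene types and coordinates came from GENCODE M21 on the build of the files, in which 15361 of the tested genes had an entry.

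Gene lists for skin cell types, pathways, stress and other cell types were fixed by name (35 lists), and 27 with at least 5 measured members were tested with camera (preset correlation 0.01 between genes, and again with the correlation estimated) and with fry, adjusted over the lists of a contrast. Camera compares a list with all other genes, and fry tests whether its members move, on balance, in 1 direction. With the estimated correlation, no list passed in any contrast, and the lowest adjusted p values were 0.22 for NFIB/X-dKO against WT, 0.49 for NFIB-cKO against WT, 0.54 for NFIX-cKO against WT, 0.40 for NFIB/X-dKO against NFIB-cKO, 0.28 for NFIB/X-dKO against NFIX-cKO and 0.56 for the non-additive contrast. With the preset correlation, the lists passing in those contrasts numbered 9, 10, 8, 10, 11 and 7. Fry called 2 lists in NFIB/X-dKO against WT and 0 in each of the other contrasts. For each list the members past the test were counted over all genes tested and adjusted over the list alone. The lists described for each contrast were chosen after the list results were seen.

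Genes were named by a rule. For NFIB/X-dKO against WT these were the 10 largest rises and the 10 largest falls past the test, with a mean TPM of at least 5 in the higher group and both libraries of 1 group beyond both of the other. In the other contrasts 5 of each were taken. Where fewer than 3 passed in a direction, the 3 with the smallest p were named as not past the test. Predicted genes and pseudogenes were skipped. The NFI genes, up to 4 members with the smallest p of each described list, and Sox9, Lhx2, Tcf7l1, Tcf7l2, Nfatc1, Foxc1, Tbx1, Cd34, Krt15 and Lgr5 in contrasts against WT were added. The result of 1 gene named by this rule is not reported here. The tests, lists, naming rule and most other settings were fixed before the data were examined.

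The steps were tested on simulated data with 200 changed genes for the NFIB/X-dKO against WT contrast. Limma recovered 11.9% of genes changed 2-fold, 88.1% of those changed 4-fold and 100% of those changed 8-fold, with 24 false calls among 15112 genes. In the simulated NFIB/X-dKO against NFIX-cKO counts, edgeR recovered 19.4%, 98.5% and 100% at those folds, with 1 false call among 18324 genes. With no gene changed, 20 draws gave a median of 2 calls (range 0 to 12) for NFIB/X-dKO against WT, 4 (1 to 10) for NFIB-cKO against WT and 2 (0 to 8) for NFIX-cKO against WT. The medians were 3.5 (1 to 11) for NFIB/X-dKO against NFIB-cKO, 3 (1 to 10) for NFIB/X-dKO against NFIX-cKO, 3.5 (0 to 15) for the non-additive contrast, and 0 (0 to 1) for edgeR. Of 40 random lists, 0 passed. The simulation used 1 dispersion for all genes and no difference between series, so its false calls set no rate for these data. Its genes were drawn independently, so the random lists do not test camera on lists of correlated genes.

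The other settings tried were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling of the TPM, a fit of the compared groups alone, the series of animal numbers (30s or 80s) as a covariate, no variance trend, and leaving out each library. For edgeR they were the size factors and the Wald test of DESeq2 1.42.0, no filter on low counts, NFIB-cKO 85 added, and limma on the same 4 libraries. A fit within series, which compares only libraries with animal numbers of the same series, a fit of protein-coding genes only, and correlations with a separate WT library as control for each group of a pair were chosen after seeing the data. In fits that left 1 library in a group, that library was assumed to vary like the other groups.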

Results

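The data were RNA sequencing of hair follicle stem cells, the cells of the follicle bulge that renew the hair, sorted from back skin of male mice at postnatal day 70, when follicles rest. There were 8 libraries in 4 groups of 2: WT (animals 34 and 82), NFIB-cKO (81 and 85), NFIX-cKO (32 and 88) and NFIB/X-dKO (33 and 36). Nfib and Nfix encode transcription factors of the nuclear factor I family, and the series title names their part in stem cell chromatin and in hair loss. Per the labels the knockout strains carried Sox9-CreER, a Cre recombinase joined to a part of the oestrogen receptor, with floxed Nfib, Nfix or both, and the NFIX-cKO mice also carried 1 floxed Nfib allele. Expected count totals were 66854625 in NFIB-cKO 85, 57826281 in NFIX-cKO 32, 63773522 in NFIX-cKO 88, 57173266 in NFIB/X-dKO 33 and 61247130 in NFIB/X-dKO 36. The depth of WT 34, WT 82 and NFIB-cKO 81 was unknown. Values below are TPM as mean ± SD (n = 2), changes are log2(TPM + 1) differences ± SE from limma unless edgeR is named, and adjusted p values come from the same fit.

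Neither targeted gene passed the test as lower in total in a group named after its loss. Nfib (chromosome 4, 82290173 to 82705750, mm10) stood at 219 ± 14.6 in WT, 263 ± 42.8 in NFIB-cKO, 174 ± 36.8 in NFIX-cKO and 383 ± 8.29 in NFIB/X-dKO. Its difference from WT was 0.25 ± 0.18 in NFIB-cKO (adjusted p = 0.649) and 0.80 ± 0.18 in NFIB/X-dKO (adjusted p = 0.0736). Nfix (chromosome 8, 84699876 to 84800344) stood at 158 ± 0.651 in WT, 151 ± 4.82 in NFIB-cKO, 131 ± 10.6 in NFIX-cKO and 137 ± 16.2 in NFIB/X-dKO, a difference from WT of -0.27 ± 0.13 in NFIX-cKO (adjusted p = 0.767) and -0.21 ± 0.13 in NFIB/X-dKO (adjusted p = 0.433). The labels do not name the deleted part, and reads from the rest of the gene count towards its total, so these totals check no label and each group name stands for its label. Esr1, the oestrogen receptor gene (chromosome 10, 4611593 to 5005614), read 0.47 and 0.33 TPM in the WT libraries and from 12.55 to 32.36 TPM in the 6 libraries labelled with Sox9-CreER. Reads from the receptor part of that transgene can count towards Esr1, and these were not told apart. No Esr1 value of these 6 libraries, and no Esr1 change, measures the mouse's own gene alone. All libraries were male by expression, with Ddx3y from 27.04 to 42.81 TPM and Xist at no more than 0.38 TPM.

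**Figure D1:**
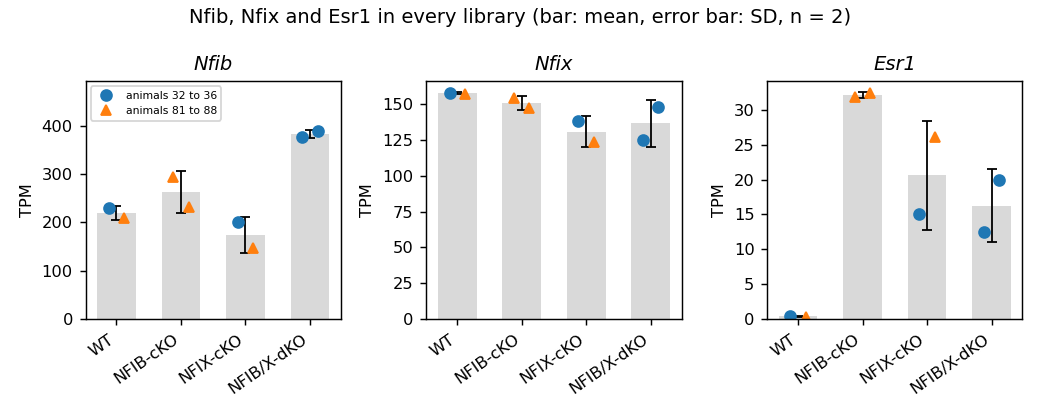
TPM of Nfib, Nfix and Esr1 by group, with bars for the mean, error bars for the SD (n = 2), circles for animals 32 to 36 and triangles for animals 81 to 88. Nfib was 383 ± 8.29 in NFIB/X-dKO against 219 ± 14.6 in WT, and Esr1 was at most 0.47 in WT.

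The libraries also differed by animal number. The first principal component, with 41.5% of the variance, separated animals 32 to 36 (the 30s) from animals 81 to 88 (the 80s), and the second, with 21.8%, separated NFIB-cKO and NFIB/X-dKO from WT and NFIX-cKO. With groups in the model, 2435 genes differed between the series, 498 higher and 1937 lower in the 80s. The series term rests on the WT and NFIX-cKO pairs, on unscaled TPM. Their median-of-ratios factors were lower in the 80s, at 0.897 against 1.08 in WT and 0.852 against 1.04 in NFIX-cKO. A lower factor means a lower median gene, so the TPM scale can account for part of this split, which was not counted after scaling. Immediate early and heat shock genes were higher in the 80s as a list (median 0.53, 2 of 25 rose, camera adjusted p = 5.08e-10, adjusted p = 0.69 with an estimated correlation), as were mitochondrially encoded genes (median 0.44, 4 of 13 rose, camera adjusted p = 1.46e-05, adjusted p = 0.43 with an estimated correlation). Relative to the mean of the 8 libraries, the immediate early list lay at 0.36 and 0.51 in WT 34 and 82. It lay at -0.95 and 0.17 in NFIX-cKO 32 and 88, so its difference came largely from NFIX-cKO 32. Of 31 epidermal differentiation genes 15 fell and 2 rose in the 80s (median -0.74), but the list did not pass (camera adjusted p = 0.224, adjusted p = 0.81 with an estimated correlation). Cell cycle genes had a median of 0.27 in the 80s (1 of 37 rose and 1 fell, camera adjusted p = 0.00107, adjusted p = 0.69 with an estimated correlation). WT and NFIX-cKO held a library of each series, whereas both NFIB/X-dKO animals were in the 30s and both NFIB-cKO animals in the 80s.

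**Figure D2:**
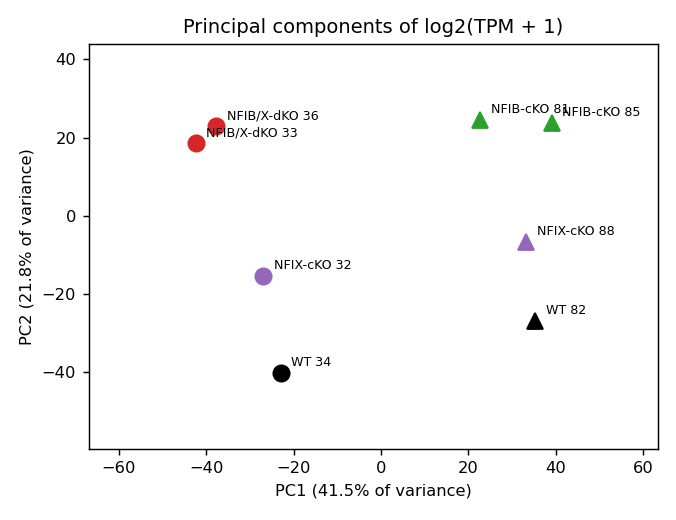
Principal components 1 and 2 of log2(TPM + 1) over the 15434 genes tested, 1 point per library, coloured by group, with circles for the 30s and triangles for the 80s. The first component (41.5%) separates the series of animal numbers.

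The comparison of NFIB/X-dKO with WT asked what the loss of both factors changed in these cells. Mest, an imprinted gene, rose from 2.35 ± 0.247 to 67.1 ± 1.40 TPM (4.35 ± 0.17, adjusted p = 0.000246), and Piezo2, a mechanically gated ion channel of touch receptors, rose from 1.99 ± 0.276 to 55.9 ± 2.55 TPM (4.25 ± 0.19, adjusted p = 0.000325). Krt24, a keratin of bulge stem cells, fell from 407 ± 75.8 to 27.7 ± 1.36 TPM (-3.82 ± 0.22, adjusted p = 0.00102). Lhx2, a transcription factor of the stem cells, fell from 303 ± 16.3 to 113 ± 12.9 TPM (-1.42 ± 0.15, adjusted p = 0.00612). The fatty acid desaturase gene Scd1 fell from 140.3 ± 53.005 to 18.6 ± 0.608 TPM (-2.79 ± 0.27, adjusted p = 0.00501). Mest lies on chromosome 6 (30723547 to 30748465), Piezo2 on 18 (63010213 to 63387183), Krt24 on 11 (99279959 to 99285262), Lhx2 on 2 (38339281 to 38369733) and Scd1 on 19 (44394455 to 44407879).

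The other large rises were those of Gpnmb, a membrane glycoprotein (3.66), Esr1 (3.59), the proton pump Atp12a (3.51), Gap43, a growth cone protein (3.36 ± 0.25), the sulfotransferase Chst9 (3.14) and Plekha6 (3.04). Rn7s1 and Rn7s2 (2.88 each) are near-identical copies that can share reads, so their values are uncertain. The large falls were those of Myoc, which encodes myocilin (-5.46), the peptide hormone Cck (-5.17), the fatty acid hydroxylase Fa2h (-4.96), the sarcosine dehydrogenase Sardh (-4.67), Ltbp2, a binding protein of latent TGF-beta (-4.40), the fatty acid elongase Elovl3 (-3.77), the lipid droplet protein Cidea (-3.58) and the adhesion molecule Cadm3 (-3.40). Ccl27b (-5.67) has near-identical copies and is uncertain. Between NFIB/X-dKO and WT 34, within the 30s, these 20 genes kept 0.887 to 1.31 times their size. Their direction there was fixed by the naming rule, and the NFIB/X-dKO libraries were the same, so this does not test the series. The calls of Rn7s1, Rn7s2 and Ccl27b ended within series.

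In all, 445 of 15434 genes passed, 250 higher and 195 lower, and 394 of them were protein coding. At an unadjusted p under 0.05 there were 2596. The median gene stood 0.16 higher in NFIB/X-dKO, and median-of-ratios scaling shifted it by -0.158. Without scaling it stood at 0.035 within series and 0.039 with the series covariate, so whether TPM or the series raised it was not tested. Scaling gave 201 higher and 241 lower, or 45.5% higher against 56.2%, and a pseudocount of 0.1 gave 201 higher and 193 lower. The count was 40 without NFIB/X-dKO 36, 49 without NFIB/X-dKO 33, 194 without WT 82, 239 without NFIB-cKO 85 and 240 without NFIB-cKO 81. Of the genes named for this comparison, the calls of Mest, Piezo2, Esr1, Gap43, Chst9, Cck, Fa2h, Sardh, Ltbp2, Krt24, Elovl3, Cidea, Timp3, Scd1, Egfl6 and Ccl27b were kept without either NFIB/X-dKO library, those of Myoc and Far2 ended without NFIB/X-dKO 36, and all others ended without each of the pair.

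**Figure D3:**
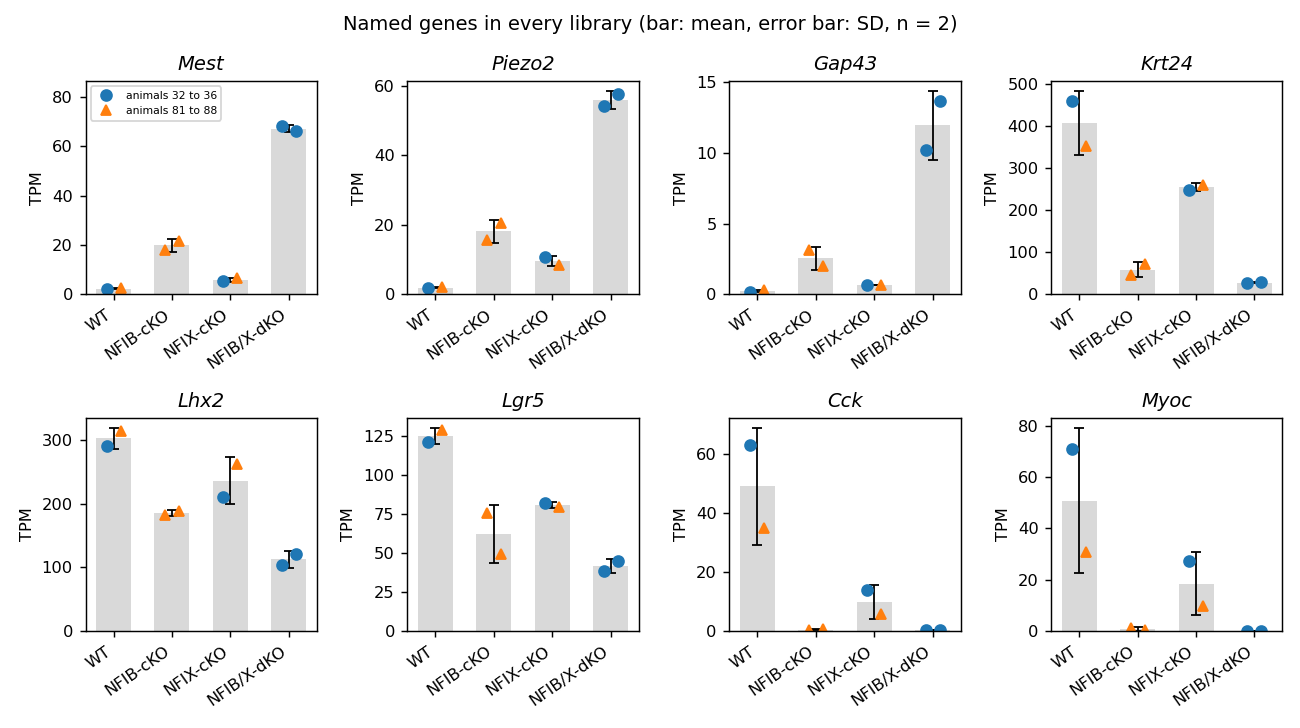
TPM of Mest, Piezo2, Gap43, Krt24, Lhx2, Lgr5, Cck and Myoc by group, with bars for the mean, error bars for the SD (n = 2), circles for animals 32 to 36 and triangles for animals 81 to 88. Krt24 was 407 ± 75.8 in WT, 58.5 ± 17.7 in NFIB-cKO, 254 ± 9.27 in NFIX-cKO and 27.7 ± 1.36 in NFIB/X-dKO.

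Of 30 genes of hair follicle stem cell identity, 6 fell and 1 rose (11 and 1 adjusted over the list alone). Beside Krt24 and Lhx2, the falls included the homeodomain protein gene Hopx (-1.45), the Wnt co-receptor gene Lgr5 (-1.57 ± 0.20, adjusted p = 0.0128) and the quiescence factor gene Foxc1 (-0.90, adjusted p = 0.0317), of which Lgr5 and Foxc1 were not called within series. Other regulators did not pass: Sox9 stood at -0.47 (adjusted p = 0.454), Tcf7l1 at -0.51, Tcf7l2 at 0.02, Nfatc1 at -0.11, Tbx1 at 0.39, Krt15 at -0.63 (adjusted p = 0.193) and Cd34, the sort marker, at -0.18 (adjusted p = 0.561). The list's median was -0.29 (camera adjusted p = 2.31e-06, adjusted p = 0.22 with an estimated correlation, fry adjusted p = 0.0208). It lay between -0.47 and -0.19 with single libraries left out.

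Sebaceous gland genes, which make and store lipid, had the most members past the test as lower of any list. Of 22 measured members 12 fell and 0 rose (15 and 1 adjusted over the list alone), among them Scd1, Elovl3, Cidea and the fatty acyl reductase gene Far2 (-2.60). Their median was -1.31 (camera adjusted p = 1.11e-16, adjusted p = 0.31 with an estimated correlation, fry adjusted p = 0.0208). Cholesterol synthesis genes had 1 fall in 23 (2 adjusted over the list alone) and a median of -0.20 (camera adjusted p = 0.0112, adjusted p = 0.71 with an estimated correlation).

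Among basement membrane and adhesion genes, 5 of 30 rose and 0 fell (9 and 1 adjusted over the list alone). They included the matrix protein genes Egfl6 (1.62 ± 0.13, adjusted p = 0.0028), Lamb1 (1.14), Tnc (1.83) and Col4a6 (0.84), the last of which was not called after scaling or within series. The list did not pass as a whole (median 0.28, camera adjusted p = 0.0848), and its median was 0.10 after scaling. Within series, against WT 34 alone, the median was 0.22, and camera called the list as higher there. Of 27 Wnt signalling genes 5 rose and 3 fell (10 and 3 adjusted over the list alone): the inhibitor gene Wif1 (1.98, adjusted p = 0.00906) and the ligand gene Wnt6 (1.99, adjusted p = 0.0324) rose, and Lgr5 and the inhibitor gene Nkd1 (-1.65) fell, with a list median of 0.53 (camera adjusted p = 0.214). Wnt6 was not called with the series as a covariate, nor Nkd1 within series or in a fit of the compared groups alone. Inner bulge and companion layer genes had 2 rises in 8 (2 rises and 2 falls adjusted over the list alone). These were Timp3, an inhibitor of matrix proteases (2.41 ± 0.19, adjusted p = 0.00256), and the keratin gene Krt17 (1.95, adjusted p = 0.0117). The list did not pass (median 0.14, camera adjusted p = 0.929), and its median was -0.04 after scaling and 0.40 within series.

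Cell cycle genes had 2 rises in 37 (6 adjusted over the list alone), of the replication gene Gins2 (0.93) and the maintenance methylation gene Uhrf1 (adjusted p = 0.0277), and both calls ended after scaling. Their median of 0.47, 0.33 after scaling, passed camera (adjusted p = 0.00213, adjusted p = 0.71 with an estimated correlation), but not without WT 34 or without NFIB/X-dKO 36, where the medians across left-out libraries lay between 0.24 and 0.70. Immediate early and heat shock genes, which were higher in the 80s, had 2 falls in 25 (2 adjusted over the list alone), of Jund (-1.03) and Hspa1b (-0.92), and a median of -0.72 (camera adjusted p = 1.05e-07, adjusted p = 0.65 with an estimated correlation). The Jund call ended within series and the Hspa1b call with the series covariate. For mitochondrially encoded genes, also higher in the 80s, 0 of 13 passed by limma, and the median was -0.29 (camera adjusted p = 0.000528, adjusted p = 0.54 with an estimated correlation). Fry did not pass it (adjusted p = 0.271), and camera did not within series (adjusted p = 0.196) or without WT 82. Of 8 measured fibroblast and dermal papilla markers, Col6a1 fell (-1.34, adjusted p = 0.00612) and Col1a1 rose (1.97, adjusted p = 0.0219), with 5 falls and 2 rises adjusted over the list alone and a median of -0.73 (camera adjusted p = 0.0275, adjusted p = 0.54 with an estimated correlation). The calls of that list and of the cholesterol list ended within series and without WT 82.

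**Figure D4:**
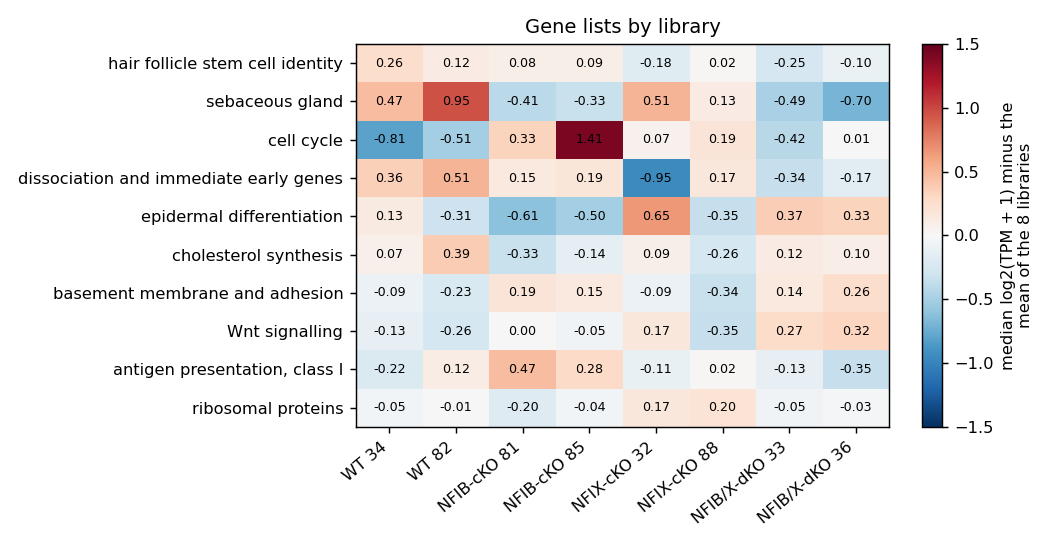
Heat map of 10 gene lists by library, as the median over a list's genes of log2(TPM + 1) minus that gene's mean over the 8 libraries. The sebaceous gland list lies at 0.47 and 0.95 in WT 34 and WT 82 and at -0.49 and -0.70 in NFIB/X-dKO 33 and 36.

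The comparison of NFIB-cKO with WT asked what the loss of NFIB alone changed. Cck fell from 49.2 ± 19.8 to 0.41 ± 0.198 TPM (-5.10 ± 0.42, adjusted p = 0.00505), Krt24 from 407 ± 75.8 to 58.5 ± 17.7 TPM (-2.80 ± 0.22, adjusted p = 0.00505), and Ltbp2 from 70.8 ± 25.8 to 4.19 ± 0.608 TPM (-3.75 ± 0.30, adjusted p = 0.00505). Piezo2 rose from 1.99 ± 0.276 to 18.1 ± 3.36 TPM (2.67 ± 0.19, adjusted p = 0.00329), and Esr1 rose by 4.56 ± 0.30 (adjusted p = 0.0022). Piezo2 was named here after its values were seen, and its call was not run under the other settings. Gpnmb (3.24) and Atp12a (2.89) also rose, and Myoc (-4.80), the amino acid transporter gene Slc43a1 (-3.10) and Sardh (-3.00) fell. The short microRNA genes Mir7655 (6.11 and 8.7 TPM in NFIB-cKO) and Mir7059 (5.43 and 7.74 TPM) were listed at 0 in all other libraries.

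The test called 111 genes, 45 higher and 66 lower (1952 at an unadjusted p under 0.05). The count was 45 within the 80s series, 200 with a series covariate, 11 without NFIB-cKO 81, 12 without NFIB-cKO 85, 34 without NFIB/X-dKO 36, 37 without NFIB/X-dKO 33 and 38 without WT 34. Within series the calls of Atp12a, Myoc, Ltbp2, Sardh, Krt24, Hopx, Elovl6, Far2, Tnc, Mir7655 and Mir7059 ended. The 10 largest changes kept 0.854 to 1.02 times their size there. Their direction was fixed by the naming rule, and the NFIB-cKO libraries were the same, so this does not test the series. Scaling ended the calls of Gpnmb, Atp12a, Scd1 and Far2.

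Sebaceous gland genes were again lower, though fry called 0 lists in this contrast. Of 22 members 5 fell and 0 rose (14 and 0 adjusted over the list alone), with Elovl6 at -1.58, Acsbg1, an acyl-CoA synthetase gene, at -1.80, Scd1 at -2.14 and Far2 at -1.83, and a median of -1.07 (camera adjusted p = 1.15e-16, adjusted p = 0.49 with an estimated correlation). Cholesterol synthesis genes had 1 fall in 23 over all genes tested (8 adjusted over the list alone), with Insig1 at -1.30 (adjusted p = 0.0732), and the list's median was -0.40 (camera adjusted p = 7.07e-07, adjusted p = 0.49 with an estimated correlation). Basement membrane and adhesion genes had 4 rises in 30 (5 adjusted over the list alone), of Egfl6 (1.56, adjusted p = 0.00554), Tnc (2.46, adjusted p = 0.0178), Col4a5 (0.91) and Col4a6 (0.89), with a median of 0.23 (camera adjusted p = 0.000716, adjusted p = 0.49 with an estimated correlation). The calls of Col4a5 and Col4a6 ended after scaling and within series. Epidermal differentiation genes had 1 fall in 31, of the elongase gene Elovl4 (-2.09, adjusted p = 0.0085), also 1 adjusted over the list alone, and a median of -0.51 (camera adjusted p = 0.00416, adjusted p = 0.67 with an estimated correlation). This list's median was lower in the 80s, the series of both NFIB-cKO animals, though not past camera, and it was -0.20 here within series. The cholesterol and epidermal lists were not called without WT 82, nor the epidermal list without NFIB-cKO 81.

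The cell cycle list stood highest in this group. By limma 0 of its 37 members passed over all genes tested, and 25 rose adjusted over the list alone, with the mitotic genes Birc5 at 2.22 (adjusted p = 0.0851), Top2a at 2.14 and Nusap1 at 1.95, and Uhrf1 at 1.04 (adjusted p = 0.0508). The median was 1.47 (camera adjusted p = 3.20e-18, adjusted p = 0.49 with an estimated correlation). Relative to the mean of the 8 libraries it was 1.41 in NFIB-cKO 85 and 0.33 in NFIB-cKO 81. Within series the median was 1.25, and 0 genes passed adjusted over the list alone. Of the 30 stem cell identity genes, Krt24 and Hopx (-1.01, adjusted p = 0.0487) fell (5 falls and 3 rises adjusted over the list alone), and the list did not pass (median -0.19, camera adjusted p = 0.0733). Within series, against WT 82 alone, the identity list's median was -0.09, but camera called the list as lower there. Not past the test were Lhx2 (-0.70, adjusted p = 0.102), Lgr5 (-1.02, adjusted p = 0.0898), Sox9 (0.41), Tbx1 (0.88, adjusted p = 0.121), Nfatc1 (0.78), Tcf7l1 (0.38), Foxc1 (-0.29), Krt15 (-0.20), Cd34 (-0.18) and Tcf7l2 (0.00). Between series, antigen presentation genes were higher in the 80s (median 0.25, 2 of 15 rose, camera adjusted p = 0.000231, adjusted p = 0.69 with an estimated correlation). In NFIB-cKO 0 of 15 rose by limma (2 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 0.000163, adjusted p = 0.49 with an estimated correlation). Melanocyte markers had a median of 0.82 over 7 (0 rises, 1 adjusted over the list alone) and myeloid markers of -0.79 over 10 (0 falls, 1 adjusted over the list alone), each with a camera adjusted p of 0.00269 and an adjusted p = 0.49 with an estimated correlation. The antigen and melanocyte lists were not called within series or without WT 34, and the myeloid list not without WT 82.

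The comparison of NFIX-cKO with WT asked the same for NFIX, in mice with 1 floxed Nfib allele. Piezo2 rose from 1.99 ± 0.276 to 9.62 ± 1.47 TPM (1.83 ± 0.19, adjusted p = 0.0287), and Mcam, a cell adhesion molecule gene, rose from 2.79 ± 0.134 to 13.2 ± 1.40 TPM (1.91 ± 0.21, adjusted p = 0.0344). Arvcf, a catenin gene, fell from 81.8 ± 10.1 to 32.005 ± 3.94 TPM (-1.33, adjusted p = 0.0393). Esr1 (3.90 ± 0.30, adjusted p = 0.00519), Tmem176a (1.28) and the sulfotransferase gene Hs3st6 (1.23) also rose, and Mir23a (-1.43) and Mir27a (-1.27), short neighbouring microRNA genes, fell.

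For this comparison, simulated libraries without a change gave a median of 2 calls and up to 8, and 10 in the separate self-test. They held no series difference, so they set no false-call rate here. In the data only 23 genes passed, 13 higher and 10 lower, and 7 of them were protein coding (1051 at an unadjusted p under 0.05). The count was 12 in a fit of WT and NFIX-cKO alone, 44 with a series covariate, 2 over protein-coding genes. It was 13 without NFIB/X-dKO 33, 13 without NFIB/X-dKO 36, 14 without WT 82, 15 without NFIB-cKO 81 and 15 without NFIB-cKO 85. Of the named calls that of Esr1 alone was kept within series. Those of Piezo2, Tmem176a, Hs3st6, Mir23a, Arvcf and Mir27a ended whichever of the 8 libraries was left out. The call of Mcam ended in 6 of those fits, and that of Esr1 without WT 34 and without WT 82. Over protein-coding genes the calls of Piezo2, Mcam, Tmem176a, Hs3st6 and Arvcf ended.

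None of the lists described here had a member past the test over all genes tested. Among the lists with at least 5 measured members, cell cycle genes had the largest shift upwards, with a median of 0.71 over 37 (0 past limma's test, 0 adjusted over the list alone, camera adjusted p = 1.83e-18, adjusted p = 0.54 with an estimated correlation), and Birc5 at 1.32 and Tyms at 0.71 (adjusted p = 0.459). Ribosomal protein genes stood 0.23 higher over 43 (0 adjusted over the list alone, camera adjusted p = 6.83e-12, adjusted p = 0.54 with an estimated correlation), with Rps7 at 0.37 (adjusted p = 0.626). Immediate early and heat shock genes, higher in the 80s, were lower (median -0.77, 0 of 25 past the test, 6 falls adjusted over the list alone, camera adjusted p = 1.03e-08, adjusted p = 0.57 with an estimated correlation). Within that list Jund had an adjusted p of 0.111 and Btg2 stood at -1.33. Relative to the mean of the 8 libraries the list lay at -0.95 in NFIX-cKO 32 and 0.17 in NFIX-cKO 88. It was not called without NFIX-cKO 32. Sebaceous gland genes had a median of -0.44 over 22 (0 past the test and 0 adjusted over the list alone, camera adjusted p = 5.16e-05, adjusted p = 0.57 with an estimated correlation), with Scd1 at -0.89 (adjusted p = 0.559). Cholesterol synthesis genes had a median of -0.37 over 23 (0 past the test, 1 fall adjusted over the list alone, camera adjusted p = 0.000389, adjusted p = 0.57 with an estimated correlation), with Insig1 at -1.25 (adjusted p = 0.233). Both lipid lists were not called without WT 82.

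Stem cell identity genes in NFIX-cKO had a median of -0.25 over 30 (0 past the test and 0 adjusted over the list alone, camera adjusted p = 0.0380, adjusted p = 0.54 with an estimated correlation). That call ended after scaling (adjusted p = 0.0734), within series, and without WT 82 or NFIX-cKO 32. Single members stood at -1.24 for Id2 (adjusted p = 0.342), -0.63 for Lgr5, -0.67 for Foxc1, -0.53 for Sox9, -0.37 for Lhx2, -0.35 for Tcf7l2, -0.26 for Nfatc1, -0.10 for Tcf7l1, 0.06 for Cd34, 0.15 for Tbx1 and 0.18 for Krt15.

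The comparison of NFIB/X-dKO with NFIB-cKO asked what the loss of NFIX added, but all NFIB-cKO animals were in the 80s and all NFIB/X-dKO animals in the 30s, so group and series cannot be told apart without the model's series term. Mest rose from 19.8 ± 2.52 to 67.1 ± 1.40 TPM (1.71 ± 0.17, adjusted p = 0.0138), and Pde9a, a cyclic GMP phosphodiesterase gene, from 0.19 ± 0.113 to 5.54 ± 1.03 TPM (2.45 ± 0.22, adjusted p = 0.00876), against 4.14 and 4.06 TPM in WT. Piezo2 rose further (1.58, adjusted p = 0.0357), and Tgm5, an epidermal transglutaminase gene, fell from 293 ± 52.955 to 108 ± 4.53 TPM (-1.42 ± 0.15, adjusted p = 0.0202). The transcript RP24-378G4.3 (-1.09) and the microRNA gene Mir6990 (-2.16) fell as well. Mir7213 was listed at 7.89 and 3.74 TPM in NFIB/X-dKO 33 and 36 and at 0 in all other libraries, and Mir7655 and Mir7059 were listed at 0 in NFIB/X-dKO. Nfib (0.55, adjusted p = 0.273) and Nfix (-0.15, adjusted p = 0.492) did not pass.

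Here 35 genes passed, 24 higher and 11 lower (2654 at an unadjusted p under 0.05). Scaling, which shifted the median gene by -0.179, gave 34 genes, 28 of them in common, and ended the calls of Mest, Piezo2 and RP24-378G4.3. A series covariate gave 22 genes and ended the calls of Pde9a, Piezo2, Tgm5, RP24-378G4.3, Mir6990, Mir7213 and Mir7059, and a fit of these groups alone gave 3086. The count was 8 without NFIB-cKO 85, 12 without NFIB-cKO 81, 9 without NFIB/X-dKO 36, 10 without NFIB/X-dKO 33, 74 without NFIX-cKO 32 and 74 without NFIX-cKO 88.

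By limma no member of the lists described passed over all genes tested. Antigen presentation genes had 10 falls in 15 adjusted over the list alone and a median of -0.69 (camera adjusted p = 3.19e-08, adjusted p = 0.63 with an estimated correlation), with H2-K1 at -1.14 and H2-D1 at -0.79 (adjusted p = 0.185 each). These class I genes are near-identical to each other, so single values are uncertain. Stem cell identity genes had 6 falls in 30 adjusted over the list alone and a median of -0.44 (camera adjusted p = 9.64e-05, adjusted p = 0.40 with an estimated correlation), with Lhx2 at -0.72 (adjusted p = 0.185). Cell cycle genes had 19 falls and 2 rises in 37 adjusted over the list alone and a median of -1.16 (camera adjusted p = 1.23e-06, adjusted p = 0.72 with an estimated correlation), with Cenpa at -1.80 (adjusted p = 0.246). Leaving out single libraries moved that median between -1.68 and -0.57. Interferon response genes had a median of -0.46 over 20 (0 adjusted over the list alone, camera adjusted p = 9.64e-05, adjusted p = 0.72 with an estimated correlation), with Oasl2 at -1.80 (adjusted p = 0.255). With single libraries left out, their median lay between -0.60 and -0.27. Epidermal differentiation genes, whose median was lower in the 80s by as much, had a median of 0.74 over 31 (0 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.72 with an estimated correlation), with Krtdap at 1.39 (adjusted p = 0.196). With the series covariate that median was 0.23. With the series covariate the calls of the identity list (adjusted p = 0.0742) and the cell cycle list (adjusted p = 0.166) ended, and that of the epidermal list ended without NFIB-cKO 81.

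The comparison of NFIB/X-dKO with NFIX-cKO asked what the loss of NFIB added, and it was the only comparison for which expected counts of both groups were used here. By edgeR, Mest rose from 397 and 585 counts to 5567 and 5819 (3.45 ± 0.258), Gap43 from 35 and 39 to 506 and 713 (3.95 ± 0.293), and Pappa, a protease gene of the insulin-like growth factor system, from 858 and 818 to 5410 and 5365 (2.61 ± 0.103, adjusted p = 0.0372). Krt24 fell from 17609 and 20726 counts to 1739 and 1967 (-3.45 ± 0.177), and Scd1 from 15440 and 13680 to 3157 and 3488 (-2.21 ± 0.115). Pde9a (5.78) and Chst9 (3.40) rose, and Myoc (-7.91), Elovl3 (-5.92), Serpina9 (-4.69), the steroid dehydrogenase gene Hsd3b6 (-4.68) and Sardh (-3.98) fell, each of them with an adjusted p of 0.0457 where no other is given. Nfib stood at 0.94 (adjusted p = 0.128) and Nfix at -0.08 (adjusted p = 0.817).

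EdgeR called 59 of 18349 genes, 22 higher and 37 lower (2701 at an unadjusted p under 0.05), and limma on the TPM of all libraries called 121, 71 higher and 50 lower, with 38 genes in common and all of those in the same direction. The split of limma's calls turned with the scaling, which shifted the median gene by -0.211 and gave 35 higher and 54 lower, or 39.3% against 58.7% higher. A pseudocount of 0.1 turned it as far, to 35 higher and 52 lower (40.2% higher). The edgeR calls all ended without NFIB/X-dKO 33 (0 genes, 813 at an unadjusted p under 0.05, limma 6) or without NFIB/X-dKO 36 (0 genes, 811 at an unadjusted p under 0.05, limma 8), and they numbered 1741 without NFIX-cKO 88 and 6939 without NFIX-cKO 32. In limma on the same 4 libraries the edgeR calls of Pde9a, Myoc, Elovl3, Serpina9, Hsd3b6, Sardh, Soat1, Acsbg1 and Elovl6 ended. Limma called 17 genes within the 30s series, 39 in a fit of the 4 libraries, 20 without NFIX-cKO 88, 30 without NFIB-cKO 81 and 30 without NFIB-cKO 85.

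Of limma's 10 largest changes, Mest, Gap43, Chst9, Myoc and Elovl3 were also among edgeR's. By limma Mest (3.31 ± 0.17, adjusted p = 0.000664), Gap43 (2.96), Gpnmb (2.82) and Chst9 (2.67) rose, with Mir7213 listed at 0 in NFIX-cKO, and Myoc (-4.02), Fa2h (-4.00), Elovl3 (-3.37), Krt24 (-3.15 ± 0.22, adjusted p = 0.00363) and Fam180a (-3.07) fell. Limma also called Nfib (1.15 ± 0.18, adjusted p = 0.0467), a call that ended within series and with the series covariate. Within series the calls of Gap43, Chst9, Myoc, Fa2h, Elovl3 and Krt24 ended too. After scaling the call of Gpnmb ended.

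Sebaceous gland genes were lower in both tests. By edgeR 6 of 24 fell (16 adjusted over the list alone), with a median of -1.21 and the esterification gene Soat1 (-1.65), Acsbg1 (-1.48) and Elovl6 (-1.61) among them. By limma 5 of 22 fell (12 falls and 1 rise adjusted over the list alone), with a median of -0.94 (camera adjusted p = 2.94e-16, adjusted p = 0.28 with an estimated correlation). Within series 0 of these 22 genes fell by limma over all genes tested (17 adjusted over the list alone), and the list's median was -1.18. Of 30 stem cell identity genes, Krt24, Hopx (-1.12) and Lhx2 (-1.06, adjusted p = 0.0389) fell by limma (7 falls and 2 rises adjusted over the list alone), and Krt24 alone by edgeR (7 adjusted over the list alone). The limma calls of Hopx and Lhx2 ended within series, and that of Lhx2 after scaling. That list's median was -0.05 and its mean -0.19 (camera adjusted p = 7.63e-05, adjusted p = 0.28 with an estimated correlation). The call ended within series, and without NFIB/X-dKO 33 the median was 0.10.

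Basement membrane and adhesion genes had 3 rises in 30 by limma (11 adjusted over the list alone), of Egfl6 (1.07), Tnc (1.97) and Lamb1 (1.11), and 0 in 33 by edgeR (6 adjusted over the list alone). The limma median was 0.46, 0.22 after scaling (camera adjusted p = 0.0392, adjusted p = 0.75 with an estimated correlation), and the call ended within series and without WT 34, WT 82, NFIX-cKO 32 or NFIB/X-dKO 36. The limma calls of Egfl6, Tnc and Lamb1 also ended within series, and those of Egfl6 and Lamb1 after scaling. Wif1 rose by 2.18 by limma and 1.95 by edgeR, the only Wnt signalling gene of 27 past either test (7 rises and 2 falls by limma and 3 and 2 by edgeR adjusted over the list alone). The limma call of Wif1 ended after scaling and within series, and the edgeR call with the size factors of DESeq2. The Wnt list had a median of 0.35 (camera adjusted p = 0.772). Ribosomal protein genes stood lower by 43 members' median of -0.22, -0.47 after scaling and -0.47 by edgeR, with 0 past either test over all genes or adjusted over the list alone (camera adjusted p = 2.94e-16, adjusted p = 0.35 with an estimated correlation) and Rps2 at -0.50 (adjusted p = 0.294).

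The non-additive contrast asked where the change in NFIB/X-dKO differed from the sum of the NFIB-cKO and NFIX-cKO changes on the log2 scale. Pde9a read 4.14 and 4.06 TPM in WT, at most 0.27 TPM in the 4 NFIB-cKO and NFIX-cKO libraries, and 4.81 and 6.27 TPM in NFIB/X-dKO (4.63 ± 0.31, adjusted p = 0.00322). Cyp2g1, a cytochrome P450 gene, stood at 4.49 ± 2.41 TPM in WT, 11.8 ± 2.33 in NFIB-cKO, 18.9 ± 1.41 in NFIX-cKO and 1.55 ± 0.516 in NFIB/X-dKO (-4.26, adjusted p = 0.0394). Hs3st6 (-1.89, adjusted p = 0.0394) and Esr1 (-4.87, adjusted p = 0.0151) stood higher than in WT in every knockout group, but in NFIB/X-dKO by less than the sum. For Esr1 a transgene carried by all knockout groups would give this pattern. Mir27a (1.45, adjusted p = 0.0999) and Rarres1 (1.80, adjusted p = 0.101) did not pass.

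For this contrast, simulated libraries without a change gave a median of 3.5 calls and up to 15, but they held no series difference. In the data it called 18 genes, 10 higher and 8 lower (1455 at an unadjusted p under 0.05), of which 5 were protein coding. The count was 9 with a pseudocount of 0.1, 61 without the filter, 7 over protein-coding genes, 6 without NFIB/X-dKO 33, 7 without NFIB/X-dKO 36, 7 without NFIB-cKO 81, 8 without NFIB-cKO 85 and 9 without WT 34. The calls of Esr1, Cyp2g1, Hs3st6, Mir7655 and Mir7059 ended with the series covariate, and scaling shifted the median gene by -0.236.

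Of the called genes that are not protein coding, most were processed pseudogenes. Gm6311 read 640.44 and 443.19 TPM in WT, at most 1.18 TPM in the NFIB-cKO and NFIX-cKO libraries, and 644.83 and 617.59 TPM in NFIB/X-dKO. Pseudogenes can share reads with their parent genes, so these values are uncertain. By limma 0 members of the lists described passed. Cell cycle genes had 24 falls in 37 adjusted over the list alone and a median of -1.85 (camera adjusted p = 1.45e-19, adjusted p = 0.56 with an estimated correlation), with Birc5 at -2.83 (adjusted p = 0.34). Antigen presentation genes had a median of -0.61 over 15 (0 adjusted over the list alone, camera adjusted p = 9.69e-09, adjusted p = 0.56 with an estimated correlation), with H2-D1 at -0.83 (adjusted p = 0.441). Cholesterol synthesis genes had 4 rises in 23 adjusted over the list alone and a median of 0.62 (camera adjusted p = 0.000181, adjusted p = 0.56 with an estimated correlation), with Hsd17b7 at 1.78 (adjusted p = 0.34), and the call ended without WT 82.

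The changes of NFIB/X-dKO against WT were compared with those of the other knockout groups. Of the 250 genes that rose in NFIB/X-dKO, 229 were higher than in WT in NFIB-cKO and 223 in NFIX-cKO, with medians of 0.76 and 0.38 against 1.45 in NFIB/X-dKO. Of the 195 that fell, 194 were lower in NFIB-cKO and 184 in NFIX-cKO, with medians of -1.07 and -0.65 against -1.61. NFIB/X-dKO and NFIB-cKO shared 38 risen and 51 fallen genes (0.729 and 0.834 if independent). NFIB/X-dKO and NFIX-cKO shared 12 and 4 (0.211 and 0.126), and NFIB-cKO and NFIX-cKO shared 5 and 9 (0.0379 and 0.0428), with 0 called in opposite directions by limma.

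All these values used the same WT libraries, which by itself makes changes alike. Across genes, which are not independent replicates, Pearson's r was 0.419 for NFIB/X-dKO and NFIB-cKO, 0.561 for NFIB/X-dKO and NFIX-cKO and 0.521 for NFIB-cKO and NFIX-cKO, and 100 simulations of unchanged groups against the same controls gave a mean of 0.503. The simulation ignored the series, in which NFIB/X-dKO and NFIB-cKO differ wholly. The covariances were 0.128, 0.133 and 0.113 against simulated values of 0.0507, 0.0509 and 0.0508.

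With separate controls, each group was set against the WT library of its own series, so that a pair shared no library. Pearson's r was then 0.497 for NFIB/X-dKO and NFIB-cKO, 0.254 for NFIB/X-dKO and NFIX-cKO and 0.319 for NFIB-cKO and NFIX-cKO. Both libraries of NFIB/X-dKO and of NFIB-cKO entered, but NFIX-cKO, which is split between the series, entered with a single library. That was NFIX-cKO 88 in its pair with NFIB/X-dKO and the other NFIX-cKO library in its pair with NFIB-cKO. The pairs thus differ in the libraries behind them, so these values of r do not rank the pairs. Of 199 genes that rose in NFIB/X-dKO against WT 34, 187 were higher in NFIB-cKO than in WT 82 (94.0%, against 64.6% of all genes tested), and 62.8% were higher in NFIX-cKO 88 than in WT 82 (43.3% of all genes tested). Of 195 that fell, 182 were lower in NFIB-cKO (93.3% against 34.97% of all genes tested) and 159 in NFIX-cKO 88 (81.5% against 55.6%). The knockout cells alone were gated on YFP, which separate controls do not remove.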

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

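Of the tests below, those of reads shared with the parent gene and of genomic DNA were set before their result was seen, and those of linkage, haplotype, the YFP gate and the series of animal numbers were chosen only after the result was seen.

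The contrast that tests whether the change in NFIB/X-dKO differs from the sum of the NFIB-cKO and NFIX-cKO changes found such a difference between groups for 18 genes. By the rule for named genes these were Pde9a (4.63), Esr1 (-4.87), Cyp2g1 (-4.26), Hs3st6 (-1.89) and the short microRNA genes Mir7655 (-3.05) and Mir7059 (-2.91), as log2(TPM + 1) differences. Each of the microRNA genes was listed at 0 in all but the NFIB-cKO libraries, so their differences are no fold changes. NFIB/X-dKO and NFIB-cKO differ wholly in series, and with the series covariate of these calls that of Pde9a alone was kept. Reads of the CreER transgene were not told apart from Esr1.

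Several of the 18 belonged to a wider set of pseudogenes, picked because both libraries of some groups read more than 4 times as high as all of the others on the TPM + 1 scale. Of these 13 pseudogenes, 0 lay within 20 Mb of Nfib or Nfix. The reads may stem from the parent genes, so their positions matter as well. Parents were found for 11 of the pseudogenes, on chromosomes 4, 11, 17 and X, whereas Nfix lies on chromosome 8. The chromosome 4 parents Rpl11, Hdac1 and Hmgn2 lie at 129516104 or beyond, more than 20 Mb from Nfib (82290173 to 82705750). The parents found thus showed no linkage to the floxed genes at that distance, and linkage over longer distances was not tested. Reads shared with the parent gene may account for part of the pseudogenes: for 7 of 11 with a parent at least 95% identical, the parent moved the other way by at least 50% of the difference. This is weak, since highly expressed parents can vary by that much anyway. Eif1 moved by -145 TPM against 5.03 for Gm10157, and Rps2 by -462 against 45.3 for Rps2-ps6 and 586 for Gm6311, and Rps2 counts for both. A candidate explanation is that strains differ at the parent genes, because all 5 parents of the 6 pseudogenes high in WT and NFIB/X-dKO (Rps2 is the parent of both Gm6311 and Rps2-ps6) lay on chromosome 17 between 10 and 36 Mb, where other genes also differed more often in that pattern (odds ratio 2.23, one-sided Fisher exact p = 0.00247, and 1.98 without Pde9a and Hs3st6, which lie there). All 3 parents for the pattern high in NFIX-cKO and NFIB/X-dKO lay in another window, on chromosome 4 (odds ratio 1.74, one-sided Fisher exact p = 0.0414 over 228 genes there), but 5 of 99 and 11 of 118 windows of these sizes held as large a share, and an effect of the knockouts stays open for single genes.

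The lower level of sebaceous gland genes in NFIB/X-dKO was weighed against the sort and the series. The YFP gate, used for the knockout libraries alone, would not by itself account for it, since the list's median was -0.94 (SE 0.226, 22 genes) between NFIB/X-dKO and NFIX-cKO, which share the gate, though the list's adjusted p was 0.28 with an estimated correlation and the SE is over genes, not animals. The fall was also present within the 30s, with a median of -1.04 (SE 0.224 over genes) between NFIB/X-dKO and WT 34 and of -1.18 against NFIX-cKO 32. Relative to the mean of all libraries, the list lay there at 0.47 in WT 34, 0.51 in NFIX-cKO 32 and -0.49 and -0.70 in NFIB/X-dKO. Between series its median was 0.11 higher in the 80s, with 0 of 22 genes past the test. Camera called the list as higher in the 80s (adjusted p = 0.00968, adjusted p = 0.69 with an estimated correlation). Both NFIB/X-dKO animals were in the 30s, so the series may add to the fall. The falls within the 30s argue against the series of animal numbers as the whole source, though each within-series comparison rests on a single other library. A change of these genes with the loss of NFIB and NFIX may therefore be a biological difference, as a hypothesis from the same data. The sort for integrin alpha 6 and CD34 without Sca-1 selects bulge cells, and whether any cells of the sebaceous gland passed it was not tested.

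A set of 8 predicted genes, picked because they were far higher in NFIB/X-dKO, lies over satellite repeats by background knowledge that was not checked here. They summed to 1160.0 and 742 TPM in NFIB/X-dKO 33 and 36, against 39.9 in WT 34, 64.4 in NFIX-cKO 32 and at most 4.29 in the 80s libraries. The sum over 1280 olfactory receptor genes, silent in this tissue, was 13.94 and 13.17 TPM in NFIB/X-dKO, 11.77 in WT 34, 10.14 in NFIX-cKO 32 and 4.91 to 6.48 in the 80s, and the lower NFIB/X-dKO value was 1.12 times the highest of the others. That is no large rise of silent genes, but it follows the order of the series, and repeats in many copies could respond more to genomic DNA, so this explanation stays open. The lower NFIB/X-dKO sum of the 8 genes was 11.5 times the higher of WT 34 and NFIX-cKO 32, but the way they were picked fixed a high ratio, so it says nothing against the series, and no biological explanation was tested.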

How the results depend on the processing

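The within-series fit, the protein-coding fit and the separate controls were chosen after the data were seen, and the others were planned. The number of genes called moved by more than 1.5 times as follows, and the cause was not tested. Some alternatives also had fewer samples or genes. Without the filter on low values it was 270 for NFIB/X-dKO against WT, 29 for NFIB-cKO against WT, 71 for NFIB/X-dKO against NFIB-cKO and 61 for the non-additive contrast. A pseudocount of 0.1 gave 23 for NFIB/X-dKO against NFIB-cKO and 9 for the non-additive contrast, and moved the correlation of the NFIB/X-dKO and NFIX-cKO changes to 0.535. A fit of the compared groups alone gave 12 for NFIX-cKO against WT, 3086 for NFIB/X-dKO against NFIB-cKO and 39 for NFIB/X-dKO against NFIX-cKO on TPM. The series covariate gave 200 for NFIB-cKO against WT, 44 for NFIX-cKO against WT and 22 for NFIB/X-dKO against NFIB-cKO. Within series it was 45 for NFIB-cKO against WT and 17 for NFIB/X-dKO against NFIX-cKO on TPM. Over protein-coding genes it was 202 for NFIB-cKO against WT, 2 for NFIX-cKO against WT, 12 for NFIB/X-dKO against NFIB-cKO, 186 for NFIB/X-dKO against NFIX-cKO on TPM and 7 for the non-additive contrast. On expected counts, the Wald test of DESeq2 gave 839, no filter gave 202, and limma on the same 4 libraries gave 39. With a separate WT control for each group, the correlation was 0.497 for NFIB/X-dKO and NFIB-cKO, 0.254 for NFIB/X-dKO and NFIX-cKO and 0.319 for NFIB-cKO and NFIX-cKO, by construction without the shared libraries. NFIX-cKO entered its pairs with a single library, a different one each time, so these correlations do not rank the pairs.

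Leaving out 1 library gave 40 to 579 for NFIB/X-dKO against WT, 11 to 157 for NFIB-cKO against WT, 13 to 18 for NFIX-cKO against WT, 8 to 74 for NFIB/X-dKO against NFIB-cKO, 6 to 105 for NFIB/X-dKO against NFIX-cKO on TPM and 6 to 16 for the non-additive contrast. On expected counts by edgeR it gave 0 to 6939 (0 without either NFIB/X-dKO library, with 813 and 811 at an unadjusted p under 0.05 and 6 and 8 calls by limma). The stem cell identity list in NFIB/X-dKO against NFIX-cKO turned from a median of -0.05 to 0.0957 without NFIB/X-dKO 33 (range -0.14 to 0.0957), and the cause was not tested. No paired analysis was possible because the animal numbers differ in every library. The series covariate and the within-series fit blocked by series instead.

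Of 123 named calls, 18 held under every alternative: those of Mest, Piezo2, Esr1, Gap43, Chst9, Cck, Fa2h, Sardh, Ltbp2, Krt24, Elovl3, Cidea, Timp3, Scd1 and Egfl6 for NFIB/X-dKO against WT, of Esr1 for NFIB-cKO against WT, of Mest for NFIB/X-dKO against NFIX-cKO on TPM and of Pde9a in the non-additive contrast. No named gene changed direction past the test, 646 of its values under an alternative lost the call, and 119 gained it. Of 33 list calls, 14 held under every alternative but the estimated correlation, which ended all 33. Leaving out NFIB/X-dKO 33 ended 89 of these 123 calls, and leaving out NFIB/X-dKO 36 also ended 89. What depth limits in the TPM comparisons was not tested, since no counts of 3 libraries were used here.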

Other observations

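Genes of wound and stressed keratinocytes and of oxidative phosphorylation followed the series of animal numbers. In the 80s, 7 of 23 wound and stress genes rose against the 30s (median 0.49, camera adjusted p = 7.35e-06, adjusted p = 0.43 with an estimated correlation), and 16 of 38 oxidative phosphorylation genes fell (median -0.32, camera adjusted p = 0.00122, adjusted p = 0.69 with an estimated correlation). These medians are on unscaled TPM, where the scale itself was lower in the 80s, so part of the fall can come from it. WT 34 correlated with NFIX-cKO 32 of its series at 0.972 and with WT 82 at 0.961, and WT 82 correlated with NFIX-cKO 88 at 0.970. Markers of other cell types measured at the level tested were 10 of 17 for myeloid and Langerhans cells, 8 of 17 for fibroblasts and dermal papilla, 7 of 11 for melanocytes, 5 of 8 for Schwann cells and nerve, 5 of 13 for T cells, 3 of 11 for muscle, 3 of 7 for erythroid cells, 2 of 12 for endothelial cells and 1 of 8 for adipocytes. Of Merkel cell markers 2 of 7 were measured, Krt8 and Piezo2.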
